A study of Mus musculus with 3 samples.

How the data were processed

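The series measured acetylation of lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, by chromatin immunoprecipitation with sequencing (ChIP-seq) in mouse myeloid-derived suppressor cells (MDSC). Per the labels' protocols, the cells were sorted as CD45 and CD11b positive, Ly6C positive, Ly6G positive or negative and F4/80 negative from subcutaneous tumours grown in immunodeficient SCID.beige mice. The growth protocol names MDA-MB-231-X1.1, a derivative of a human breast cancer line, and CT26, a mouse colon carcinoma line. The titles mark both ChIP libraries as TNBC. Mice received vehicle or 25 mg/kg of the CBP/EP300 bromodomain inhibitor GNE-781 by mouth, 2 doses a day for 7 days. The labels do not say how many mice stand behind a library. There were 3 libraries: 1 H3K27ac library from vehicle-treated mice, 1 from inhibitor-treated mice, and 1 pooled input, whose values were not used here because the table analysed has no column for it. Chromatin was fixed with 1% formaldehyde, and libraries were sequenced as paired reads of 150 bp with fragments of about 380 bp, per the labels' protocols.

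BWA and SICER are named in the submitters' processing notes, with the genome builds hg19 and dm3, and neither versions nor settings are given in the sources used here. Per the labels' protocols, a constant amount of Drosophila chromatin and an antibody against the fly histone H2A.v were added to each reaction for spike-in normalization. The spike-in counts and the factors used are not given in the sources used here. The deposited table lists 22399 regions, formed by merging the intervals called in each library. For each region and library it gives an average signal, a peak signal and whether an interval was called in that library. Both kinds of deposited signal are fragment pileup, and whether the authors' values include a scaling by the spike-in is not known. The coordinates are those of the mouse and not of hg19. Of 27781 pairs of a region and a gene with a current symbol, 99.99% lay on the gene's chromosome in GRCm38 and 86.9% gave the gene start within 1 kb of its place in GRCm38, so GRCm38 is named for the coordinates, which are printed as the table gives them. Of 13443 gene symbols in the table, 12198 are current symbols of the reference gene table and 862 are older symbols of a single gene.

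Whether a deposited average includes empty stretches was tested on its values. The average multiplied by the number of 32 bp bins of the region, or by 1 bin fewer, was whole within the rounding of the table for 95.9% of regions in the vehicle library and for 49.9% in the inhibitor library. No average lay between 0 and 1. Both properties are those of a mean over the bins that hold at least 1 fragment. Such a mean overstates weak signal, and so the signal of the inhibitor library more than that of the vehicle library. The deposited promoter count of a region matched, in 99.99% of regions, an overlap with the stretch from 7500 bp upstream to 2500 bp downstream of a gene start, and that definition was used.

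The measure compared was log2(inhibitor signal + 1) minus log2(vehicle signal + 1) per region, from the average signals as deposited. The pseudocount of 1 was used because 1 region has a value of 0, and it understates differences at weak regions. With 1 library per treatment there is no replicate error, so no test was run, no p-value is given, and regions are described by a rule of size (at least 2-fold lower or higher). The number of sequenced fragments is not known from the table, so the depth is unknown and no counting interval is given. A count model was not used because the values are signal, not counts.

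A gene took the value of the region with the highest mean signal of both libraries among the regions the table assigns to it. With peak signal in place of the average, that region was chosen again by peak, so it can be another region of the gene. Before the data were examined, 15 gene lists with 388 different genes were fixed, and 303 of these genes had a region. Symbols were matched without regard to case, and 3 genes were found under an older symbol. The median of each list was placed among 10000 random gene lists of the same size, drawn within 10 classes of mean signal. That percentile describes these 2 libraries and is not a p-value. The genes named were also fixed by rule before the data were examined. They are the 10 genes with the largest difference in each direction among regions at or above the median signal, the lowest and highest member of each list, and a fixed set that includes Arg1, Nos2, Ido1, Cd274, Stat3, Stat5a, Stat5b, Crebbp and Ep300 where measured. Of the genes these rules take, 2 are not reported here, and the list medians and counts include them. Other members of a list are named as examples chosen after their values were seen.

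Alternatives fixed before the data were examined were peak signal, a pseudocount of 10 percent of the median signal (0.990), ratios recentred on the median of all regions, a filter on weak regions, 1.5-fold and 3-fold thresholds, other definitions of promoter, a gene's mean over its regions, a gene's strongest promoter region, and autosomes alone. Added after seeing the data were no pseudocount, averages with empty bins put back (the largest number of bins, out of those in the region, that makes the sum whole), regions called in both libraries, other rankings of the regions, other matching of random lists, each region counted once per list, and current symbols alone. The calculations were tested on simulated data. Of 100 regions made 4-fold lower among 22399, 100% were recovered, and 0.0405% of unchanged regions passed 2-fold. That simulation used recentred ratios without a pseudocount, and a noise level that was chosen and not estimated from the libraries. Its rates follow from that choice. They check the calculation and are not error rates of the counts given here, as deposited or recentred. On 5000 simulated regions, averages over filled bins were 0.14 too high in log2, and 0.00 at the median after the bins were put back, with the exact number of bins found in 76.3% of regions. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.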

Results

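H3K27ac was profiled in MDSC sorted from tumours of mice given vehicle or the CBP/EP300 bromodomain inhibitor GNE-781. CBP and EP300 are paralogous acetyltransferases that acetylate H3K27, and their bromodomain binds acetylated lysine. The series asks how this bromodomain regulates tumour-associated myeloid cells, and the comparison here is the H3K27ac signal with inhibitor against vehicle. The data comprise 1 library per treatment and 22399 regions on 20 chromosomes, with a median length of 1420 bp. All values are single measurements without replicates, so the differences describe these 2 libraries. The depth of the libraries is unknown, and signal is given as the deposited fragment pileup averaged over a region. Whether the pileup includes a scaling by the spike-in is not known, and the size of the difference over all regions depends on it.

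Nearly all regions were called in the vehicle library alone. An interval was called in 22310 regions with vehicle and in 2298 with inhibitor. Of the 22399 regions, 20101 (89.7%) were called in the vehicle library alone, 2209 (9.86%) in both and 89 (0.397%) in the inhibitor library alone. Regions called in both libraries were strong and broad. Their median vehicle signal was 28.9 and their median length 2533 bp, against 13.9 and 1344 bp for regions called with vehicle alone. Of the regions called in both, 80.9% overlapped a promoter and 74.7% a CpG island, compared with 48.8% and 34.4% of those called with vehicle alone. The 89 regions called with inhibitor alone were short, with a median of 326 bp, and 29 of them overlapped a promoter.

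H3K27ac signal was lower with inhibitor in 22325 of 22399 regions (99.7%). The mean signal was 17.1 with vehicle and 4.86 with inhibitor, a ratio of 3.52, and the medians were 14.5 and 4.67. The median log2 difference was -1.61, with quartiles of -1.87 and -1.33, and 20931 regions (93.4%) were at least 2-fold lower whereas 31 were at least 2-fold higher. Without a pseudocount the median corresponds to a 3.52-fold lower signal. All 74 regions with a higher signal were among those called with inhibitor alone. Medians of the 19 autosomes lay between -1.66 and -1.56, and the median of the 327 regions on chromosome X was -1.49. The region set itself leans on the vehicle library, because a called interval with vehicle had an average signal of at least 8.85 whereas the inhibitor signal was free to take any value. A constant factor between the libraries is part of every ratio, and recentring on the median of all regions left 83 regions at least 2-fold lower and 185 at least 2-fold higher.

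**Figure D1:**
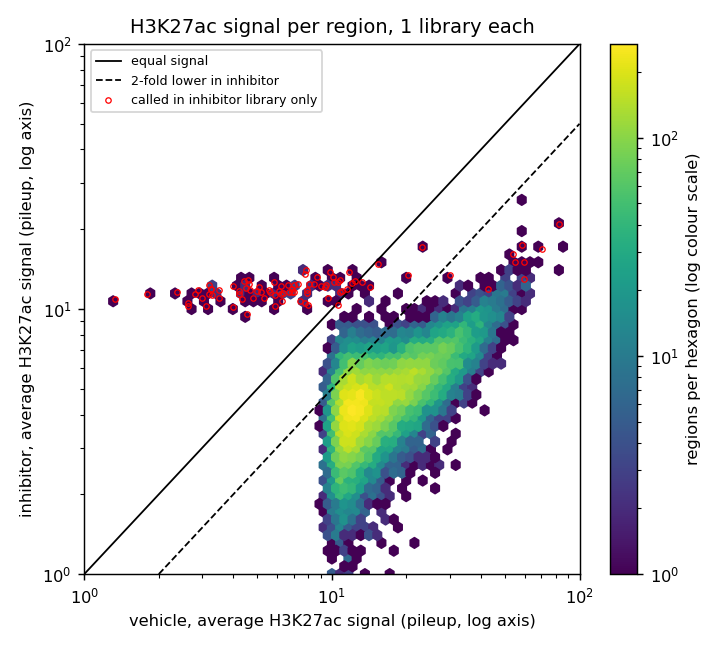
Average H3K27ac signal (fragment pileup, log axes) of each region in the vehicle library (x) and the inhibitor library (y), 1 library each; colour gives the number of regions per hexagon, the solid line equal signal, the dashed line a 2-fold lower signal with inhibitor, and red circles the 89 regions called in the inhibitor library alone. The 1 region with a value of 0 is not drawn. Most regions lie below the dashed line, and the 74 regions above the solid line are red.

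The difference was larger at promoters and at strong and broad regions than at distal, weak and narrow ones. The 11629 promoter regions had a median log2 difference of -1.71 (median signal 17.7 with vehicle and 5.11 with inhibitor), and the 10770 other regions -1.52 (12.9 and 4.26). Regions with a CpG island had a median of -1.76 and those without of -1.53. Across 4 classes of equal size by mean signal, from weakest to strongest, the medians were -1.51, -1.39, -1.60 and -1.91. Across 4 such classes by length, from shortest to longest, they were -1.42, -1.52, -1.67 and -1.77. Promoters are stronger regions. Within 10 classes of vehicle signal, the promoter median differed from that of other regions by between -0.05 and 0.09, and the largest gap of CpG island over other regions was 0.23, in the weakest class. The order by signal depends on the library that ranks the regions, since the strongest minus the weakest class was -0.40 when ranked by mean signal and 0.145 when ranked by inhibitor signal alone. Intervals called with inhibitor were found in 36.1% of the strongest class and in 0.411% of the weakest.

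**Figure D2:**
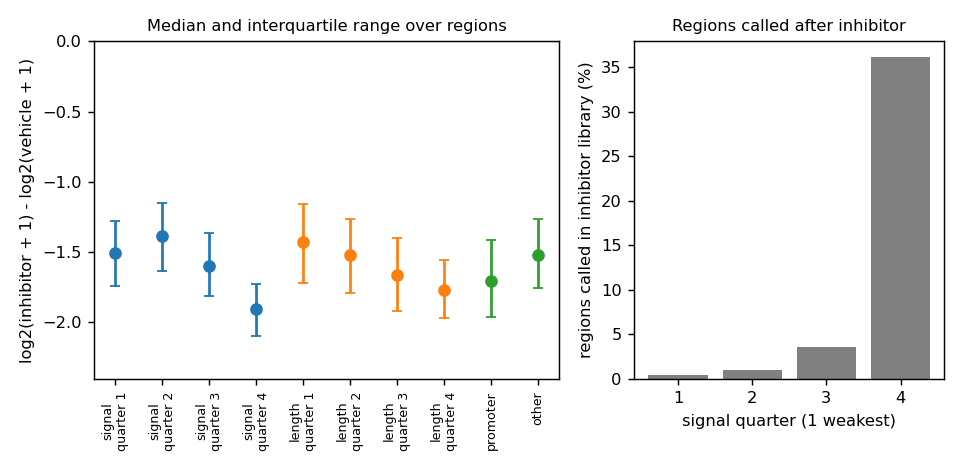
Left, median (points) and interquartile range (bars) of the log2 difference in H3K27ac signal, log2(inhibitor + 1) minus log2(vehicle + 1), over the regions of 4 classes by mean signal, 4 classes by length (1 is the weakest or shortest), promoter regions and other regions. Right, percent of the regions of each signal class with an interval called in the inhibitor library, which was 36.1% in the strongest class.

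For the genes of the fixed set that had a region, the strongest region was lower with inhibitor, like 99.7% of all regions. The strongest of the 4 signal classes had a median of -1.91, close to the values of Stat3, Stat5a and Cd274 given here. At Stat3, a transcription factor that drives suppressive functions of myeloid cells, the region at the gene start (chromosome 11, 100938132 to 100940467, GRCm38) had a signal of 48.8 with vehicle and 11.8 with inhibitor (log2 difference -1.96), and it was still called with inhibitor. The strongest region of both Stat5a and Stat5b (chromosome 11, 100860180 to 100861722) lies in Stat5a, 1600 bp from its start. Its signal was 23.3 with vehicle and 5.64 with inhibitor (-1.87). It lies 10366 bp from the start of Stat5b in the deposited annotation, and the 3 regions nearest that start stood at -1.88, -2.09 and -1.41. In GRCm38, however, Stat5b spans 100780731 to 100859004, with its upstream end beside Stat5a. The region next to that end (100859071 to 100860044) stood at -1.63. The region at the start of Cd274 (chromosome 19, 29365958 to 29368152), which encodes the checkpoint ligand PD-L1, had signals of 24.1 and 5.53 (-1.94). With the mean of its regions Cd274 stood at -1.63, and with peak signal at -1.66. At Nos2, the inducible nitric oxide synthase, the region 4171 bp upstream (chromosome 11, 78915600 to 78917777) had signals of 14.8 and 6.23 (-1.13), a smaller difference than the median region and 0.48 on the recentred scale. No region of the table analysed was assigned to Arg1 or Ido1. The targets of the drug were themselves covered. The promoter region of Ep300 (chromosome 15, 81584351 to 81587261) had signals of 40.4 and 9.13 (-2.03) and was called with inhibitor, and the strongest region assigned to Crebbp (chromosome 16, 4076915 to 4078427), which lies 135733 bp from its start beside Trap1, had signals of 27.6 and 5.49 (-2.14). The strongest region at its own promoter stood at -1.40, and the mean of its regions at -1.77.

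**Figure D3:**
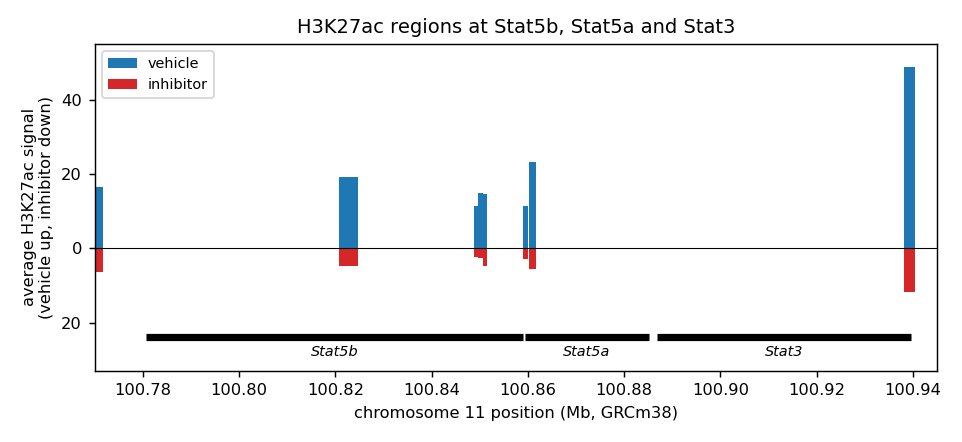
Average H3K27ac signal (fragment pileup) of the regions at Stat5b, Stat5a and Stat3 on chromosome 11 (x axis in Mb, GRCm38), with the vehicle library drawn upward in blue and the inhibitor library downward in red on the same scale; bar width is the region's length and black bars are the genes. Each of the 8 regions is lower with inhibitor, with the tallest, at the start of Stat3, at 48.8 with vehicle and 11.8 with inhibitor.

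H3K27ac regions covered myeloid genes and few genes of other lineages. All 24 neutrophil identity genes and 31 of 32 myeloid transcription factor genes had a region, against 6 of 28 T, B and NK cell genes and 6 of 24 stromal, endothelial and tumour epithelial genes. Of 24 monocyte genes, 17 had a region, as did 21 of 28 genes of mature macrophages and dendritic cells and 9 of 22 genes of alternatively activated macrophages. Few T, B, NK or tumour epithelial genes could follow from the design, since the mice were immunodeficient and the breast cancer line named is human. The counts therefore do not measure the purity of the sorted cells. A region can be assigned to a neighbour of the gene it serves. The strongest region of Cd3g, a T cell receptor component, lies 14973 bp from its start and is shared with Ube4a.

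In all 15 lists the median H3K27ac difference was below 0, and 3 lists lay below the 2.5th percentile of random gene lists matched on signal. Of all 13443 genes with a region, 12914 were at least 2-fold lower, so the counts of such genes per list say little by themselves. The interferon response list, antiviral and antigen processing genes, had the lowest median, -2.08 over 27 genes (percentile 0.580), and each of its 27 genes was at least 2-fold lower. Its lowest member was Oas1a, an antiviral synthetase, with a signal of 22.8 with vehicle and 2.89 with inhibitor (-2.61), and its highest was Oasl1 with 15.0 and 6.67 (-1.06; -1.66 with peak signal), at a region 19147 bp from its start. Mx1, an antiviral GTPase, had -2.30, and Tap1, Psmb8 and Psmb9, which serve peptide presentation, share 1 region with 43.0 and 7.745 (-2.33). The list of mature macrophages and dendritic cells had a median of -1.95 over 21 genes (percentile 0.110), all at least 2-fold lower. Its lowest member was Cd74, the invariant chain of MHC class II, with 22.1 and 3.29 (-2.43; -1.62 with the mean of its regions), beside H2-Ab1 at -2.21, and its highest was C1qc with 16.9 and 5.92 (-1.37), in a region shared with C1qa and C1qb. The 6 stromal, endothelial and tumour epithelial genes had a median of -1.92 (percentile 2.09), between Vwf at -2.12 and Kdr at -1.51. With the mean of all regions of a gene no list lay below the 2.5th percentile (5.73 for interferon response, 4.68 for mature macrophages and dendritic cells, 14.3 for the stromal list). With peak signal in place of the average, the macrophage and dendritic cell list stood at percentile 45.6 and the interferon list at 2.64. With promoter regions alone the interferon list stayed below that percentile (median -2.02), whereas the macrophage and dendritic cell list stood at 3.43 and the stromal list at 61.0. The stromal list also stood at 6.63 with weak regions left out and at 2.51 with no pseudocount.

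The list of NF-kB and inflammatory cytokine genes lay at the other end, with a median of -1.71 over 24 genes (percentile 97.7). Each of the 24 was at least 2-fold lower. Nfkbia, the NF-kB inhibitor IkB-alpha, had a signal of 31.4 with vehicle and 4.79 with inhibitor (-2.48), whereas the neutrophil chemokine genes Cxcl3 (13 and 4.83, -1.26), Cxcl1 and Cxcl2 (1 shared region, -1.30) had smaller differences. With the mean of all regions of a gene the list stood at percentile 64.9, with promoter regions alone at 58.7, and with peak signal at 95.55. On the recentred scale Cxcl3 was above 0 (0.34).

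The remaining 11 lists lay within the central range of random lists. The MDSC suppressive effector list had a median of -1.64 over 21 genes (percentile 87.7), with 20 genes at least 2-fold lower. Hmox1, heme oxygenase 1, had 22.5 and 4.39 (-2.12; -1.59 with the mean of its regions). Mmp9, a matrix metalloprotease, had 13.7 and 7.27 (-0.83) at a region 6676 bp upstream, the member that missed 2-fold. With the mean of its regions Mmp9 stood at -1.17. S100a8 and S100a9, subunits of calprotectin, had -1.57 and -1.64. The JAK-STAT list had a median of -1.90 over 32 genes (percentile 48.1), with 31 at least 2-fold lower. Jak1 had 37.0 and 7.02 (-2.24; -1.77 with the mean of its regions), and Socs1, a feedback inhibitor of cytokine signalling, had -2.18. Jak3 had 12.1 and 7.46 (-0.63) at a region 17177 bp from its start. The Jak3 value belongs to that region, with -1.60 for its promoter regions alone and -1.28 for the mean of its regions. With peak signal another region of Jak3 was strongest, at -1.92, whereas the peaks of the region given here were 20 and 12. The median of the neutrophil list was -1.64 (percentile 52.3), with 20 of 24 genes at least 2-fold lower. That list ran from Cebpd at -2.34 (-1.85 with the mean of its regions) to Mmp9. The monocyte list had a median of -1.87 (percentile 10.6), with 16 of 17 genes at least 2-fold lower. It ran from Nr4a1, a nuclear receptor of patrolling monocytes, with 31.8 and 5.45 (-2.35; -1.43 with the mean of its regions) at a region 17373 bp from its start, to Chil3, listed under its older symbol Chi3l3, with 10.8 and 4.93 (-0.99). Chil3 was also the highest of the 9 alternatively activated macrophage genes (median -1.64, percentile 40.6), and Tgm2 the lowest at -2.29 (-1.66 with the mean of its regions). On the recentred scale, Mmp9, Jak3 and Chi3l3 were above 0 (0.77, 0.98 and 0.61).

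The 31 myeloid transcription factor genes had a median of -1.93 (percentile 44.7, but 98.1 with peak signal), and all were at least 2-fold lower, from Nr4a1 to Gfi1, a transcriptional repressor needed for neutrophil differentiation, with 16.5 and 6.99 (-1.13; 0.48 recentred). Spi1, the myeloid master regulator PU.1, had 40.6 and 8.63 (-2.11) at a region 10979 bp upstream. The 26 acetylation writers, erasers and readers had a median of -1.91 (percentile 18.1), from Kat6a at -2.22 to Hdac1 at -1.13 (0.48 recentred; 27927 bp from its start), and all were at least 2-fold lower. With promoter regions alone Hdac1 stood at -1.75, a larger difference than the median region. The T, B and NK cell list had a median of -1.77 over 6 genes (percentile 25.2), from Cd3g at -2.30 to Cd79b at -1.29 (0.32 recentred). Genes of MYC and the cell cycle had a median of -1.76 over 26 (percentile 64.5), with 25 at least 2-fold lower, from Max with 40.4 and 7.83 (-2.23; -1.59 with the mean of its regions) to Top2a at -0.92 (0.69 recentred). Hypoxia and glycolysis genes had a median of -1.77 over 25 (percentile 78.8), all at least 2-fold lower, from Higd1a at -2.33 to Bnip3 at -1.27 (0.34 recentred). With peak signal another region of Bnip3 was strongest, at -1.91, whereas the peaks of the region given here were 26 and 11. Ribosomal protein and housekeeping genes had a median of -1.89 over 30 (percentile 26.2), with 29 at least 2-fold lower, and Rpl5 was the lowest with 22.7 and 2.89 (-2.61).

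**Figure D4:**
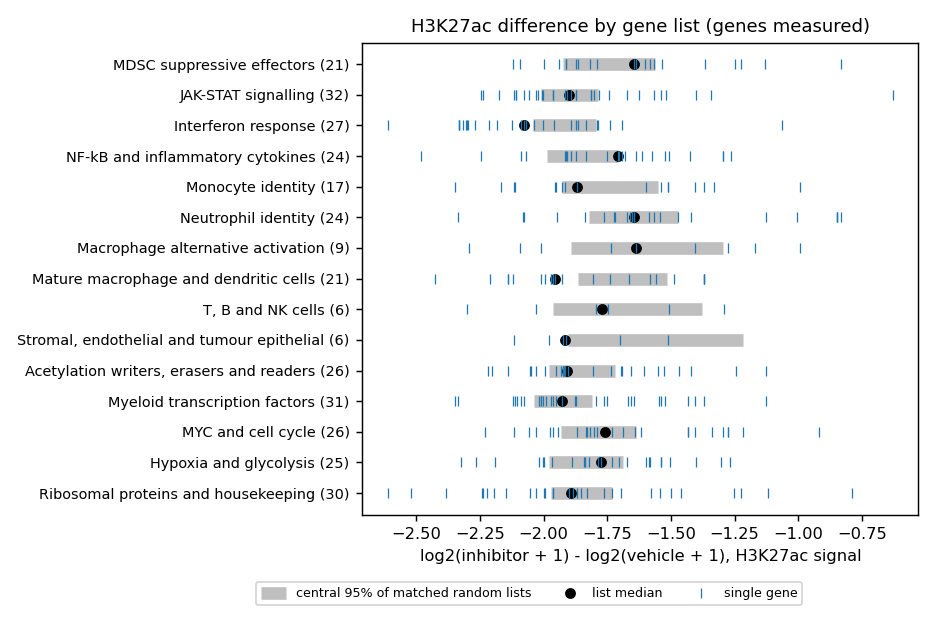
Log2 difference in H3K27ac signal, log2(inhibitor + 1) minus log2(vehicle + 1), for 15 gene lists with the number of genes measured; blue ticks are genes at their strongest region, black points list medians, and grey bars the central 95% of 10000 random lists matched on signal. The interferon response list (-2.08), the mature macrophage and dendritic cell list (-1.95) and the stromal list (-1.92) lie left of their bars, and the NF-kB list (-1.71) at the right end of its bar.

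Over all 13443 genes with a region, the median log2 difference at the strongest region was -1.78. Of these genes, 12914 were at least 2-fold lower and 13 at least 2-fold higher. Among genes at or above the median signal, the 10 largest differences were at regions within 1039 bp of the gene start, except for 3110021N24Rik, whose region lies 60569 bp from its start. 3110021N24Rik (chromosome 4, 108779727 to 108780710) had a signal of 31.8 with vehicle and 2.65 with inhibitor (-3.17), and Ncoa1, a nuclear receptor coactivator that binds CBP (chromosome 12, 4476864 to 4477233), had 26.8 and 2.10 (-3.16), a 12.7-fold ratio. The Ncoa1 region is 369 bp long, below the mean fragment of 380 bp, and whether fragments stacked at a single place there was not tested. The region at Mirlet7i (chromosome 10, 122984993 to 122986113) had 26.4 and 2.37 (-3.02). They were followed by Zranb2 (40.2 and 4.21, -2.98), Man1a2 (26.5 and 2.59, -2.94), Larp1 (23.1 and 2.19, -2.92), Minos1 (29.2 and 3.02, -2.91), Eif2s3x (26.3 and 2.73, -2.87), Ndufa10 (30.5 and 3.37, -2.85) and Eif3j1 (29.5 and 3.25, -2.85). With the mean of all regions of the gene, Ncoa1 (-2.31), Larp1 (-1.99) and Man1a2 (-1.85) were less low, and with peak signal Mirlet7i (-3.81) and Ndufa10 (-3.78) were lower still.

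The 74 regions with a higher signal were 244 to 510 bp long, and the largest log2 difference, 2.35, was at a region with 1.33 with vehicle and 10.9 with inhibitor and no assigned gene. Nkd1, a regulator of Wnt signalling, had the largest gain among genes at or above the median signal (chromosome 8, 88521640 to 88521931, 7.78 with vehicle and 13.6 with inhibitor, 0.73). The others were Dlx6as2 (0.70), 1110008J03Rik (0.55), Abcg2 (0.52), Cd163l1 (0.50), Zbtb8b (0.49), Sfrp4 (0.46), B230344G16Rik (0.34), Pde4d (0.34) and Coro2a (0.24). The filter on signal used the mean of both libraries. None of these regions, Nkd1 included, had a called vehicle interval. Their vehicle signals were at most 10.8 (Coro2a), under the vehicle median of 14.5, so they are not gains at regions strong with vehicle. With the mean of all regions of the gene, 1110008J03Rik (-0.85), Pde4d (-1.18) and Coro2a (-1.23) were lower with inhibitor.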

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

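The median over all regions stayed below 0 under each alternative that keeps the level of the deposited values: -1.61 with peak signal, -1.65 with weak regions left out, -1.82 with no pseudocount, -1.66 with empty bins put back and -1.87 over regions called in both libraries. Recentring sets it to 0.00 by construction. At the 3-fold threshold 11661 regions were lower and 11 higher, and at 1.5-fold 51 were higher. At least 2-fold lower were 83 regions after recentring and 2151 of those called in both libraries. At least 2-fold higher were 185 after recentring, 10 with weak regions left out and 0 of those called in both. Among regions whose higher signal was at or above the median, 9040 were called with vehicle alone and 12 with inhibitor alone. Promoter and other regions had medians of -1.78 and -1.46 with peak signal, -0.10 and 0.089 recentred, -1.90 and -1.73 with no pseudocount, and -1.75 and -1.56 with empty bins put back, and promoters -1.74 with weak regions left out. From the weakest to the strongest of 4 signal classes the medians were -1.39, -1.35, -1.63 and -2.06 with peak signal, 0.10, 0.22, 0.0094 and -0.30 recentred, -1.38, -1.49, -1.70 and -1.95 with weak regions left out, -1.76, -1.58, -1.78 and -2.07 with no pseudocount, and -1.56, -1.43, -1.64 and -1.95 with empty bins put back. The strongest minus weakest class was -0.61 ranked by vehicle signal and turned to 0.145 ranked by inhibitor signal. Noise in the ranking library could move it so, but was not measured. From the shortest to the longest class the medians were 0.18, 0.0871, -0.0593 and -0.16 recentred, -1.37, -1.62, -1.73 and -1.78 with weak regions left out, -1.64, -1.72, -1.86 and -1.95 with no pseudocount, -1.49, -1.57, -1.71 and -1.79 with empty bins put back, and -1.49 and -1.78 for the shortest and longest with peak signal. The number of lists below the 2.5th percentile was 0 with the mean of all regions of a gene, 1 with promoter regions alone (interferon response), 1 with peak signal (the stromal list), and 2 each with weak regions left out and with no pseudocount, where the stromal list stood at percentile 6.63 and 2.51. The number above the central range was 0 with the mean of all regions, 0 with promoter regions alone and 0 with no pseudocount, and with peak signal the myeloid transcription factor list took the place of the NF-kB list. Named genes above 0 after recentring, by construction of the scale, include Jak3 (0.98), Mmp9 (0.77), Top2a (0.69), Chi3l3 (0.61), Oasl1 (0.54), Hdac1 (0.48), Gfi1 (0.48), Nos2 (0.48), Cxcl3 (0.34), Bnip3 (0.34), Cd79b (0.32), C1qc (0.24) and Kdr (0.10). With peak signal Pde4d (-0.81) and Coro2a (-2.03) were lower, at other regions of these genes that were strongest by peak. At the regions of their gains the peaks were higher with inhibitor (14 and 15 for Pde4d, 15 and 19 for Coro2a). With the mean of all regions 1110008J03Rik (-0.85), Pde4d (-1.18) and Coro2a (-1.23) turned lower, and the cause was not tested beyond that. No paired analysis was possible because each treatment has 1 library, and no library could be left out. The depth is unknown, so differences between genes with an inhibitor signal of a few fragments carry an error that cannot be stated.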

Other observations

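Etv6, an ETS family repressor, had the most H3K27ac regions of any gene, 36, a count that is not corrected for gene length, with a median log2 difference of -1.73, and 2 of them were called with inhibitor. Zmiz1, a transcriptional coactivator, had 31 (median -1.43, 4 called with inhibitor), Cmip 30 (-1.46, 2 called) and Asap1 27 (-1.47, 2 called). Rin3 had 23 (-1.36, 0 called), Ccdc88c 21 (-1.40, 1 called) and Runx1, a haematopoietic transcription factor, 20 (-1.64, 1 called).

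Intervals called with inhibitor were compared with random lists matched on signal for all 15 lists, a comparison chosen after the data were seen. Of the 21 MDSC suppressive effector genes, 8 (38.1%) had their strongest region called with inhibitor, against 19.99% on average in random lists (percentile 99.3), and the list stood at percentile 98.8 when length was matched too. The 8 include Cd274, Ptgs2, Arg2 and Il4ra. The value of 99.3 was the highest percentile of the 15 lists. The median difference of this list also lay on the smaller side (percentile 87.7, and 96.6 with peak signal), and the share called is not separate from that. Of the NF-kB and cytokine genes, 12 of 24 were called (32.4% in random lists, percentile 99.1; 96.4 with length matched), which is not separate from the smaller difference of that list. Of the JAK-STAT genes, 16 of 32 were called (36.7% in random lists, percentile 96.9; 97.9 with each region counted once and 85.6 with length matched).

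Of the tests below, those on empty bins and on ranking noise were set before their results were seen, and the others after. The first pattern is the lower signal in 22325 of 22399 regions. Picking regions by calls in the vehicle library would raise the vehicle signal, but the 2298 regions called in the inhibitor library had a median log2 difference of -1.85. That argues against it as the whole cause at those regions. Of them, 2209 were also called with vehicle, and the 89 called with inhibitor alone had a median of 0.71. The value does not reach the 20101 weaker regions called with vehicle alone, for which the question stays open. Library scaling, depth and ChIP yield cannot be told apart from an effect of the inhibitor, since 0 columns of the table hold an input or spike-in value and each treatment has 1 library. A loss of acetylation with inhibitor is the hypothesis the design names, and it stays open with them.

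The second pattern is the larger difference in stronger regions. Leaving out empty bins may flatten weak regions, but the strongest minus the weakest of 4 classes of vehicle signal was -0.56 before and -0.54 after the bins were put back. Noise in the ranking signal could move the pattern, though the noise was not measured. Ranking by inhibitor signal turned it to 0.31 without a pseudocount. CpG island regions, a class not read from the signal, differed from other regions by a median of -0.20 with empty bins put back, which argues against noise as the whole cause. A single scaling factor for all regions would shift these averages alike and leave no such gap, so the -0.20 argues against it as the whole cause too. At equal vehicle signal the gap was mostly of the other sign. Within 10 classes of vehicle signal, with a pseudocount, it was above 0 from the weakest class (0.23) through class 8 (0.03). In classes 9 and 10, the strongest, it was -0.04 and -0.08. These values can also move with noise in the vehicle signal, which was not measured. A higher share of background in the inhibitor library, which would hold up weak regions, and a stronger effect of the drug at strong regions were not tested.

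The third pattern is the regions called with inhibitor alone, which fall into separate kinds. The 74 that were higher with inhibitor had a median length of 314 bp and lay between 244 and 510 bp, with vehicle signals of 1.33 to 12.4 and inhibitor signals of 9.56 to 14.0. A length below the mean fragment of 380 bp is consistent with stacks of fragments at a single place, which may be chance or amplification, and no biological explanation was tested. Another 9 were at least 2-fold lower with inhibitor and had vehicle signals of 29.9 to 82.3, at or above the 93.4th percentile of all regions, yet no called vehicle interval, and the other 6 lay between, with vehicle signals of 10.6 to 23.0. The 9 include 4 regions at Neat1, a nuclear long noncoding RNA, and 2 near Btbd19 and Plk3, and why the vehicle library has no interval there was not tested.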
